A study of Mus musculus with 48 samples.

How the data were processed

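Nuclei were isolated from a block of cortex and hippocampus taken beside the lesion, on the injured side of the brain of Swiss Webster mice, and their RNA was counted by droplet sequencing (10x Genomics 3' chemistry). The series holds 48 samples in 8 groups: males and females, each as sham sedentary, CCI sedentary, CCI with low exercise and CCI with high exercise, where CCI is controlled cortical impact, a mechanical model of traumatic brain injury. The dose and timing of exercise and the time from injury to collection are not given in the sources used here.

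The deposited matrices hold counts (raw UMIs per gene and barcode, not normalised), made by the authors with Cell Ranger 7.0.1 on genome build GRCm38 (mm10) per the labels. The deposited barcode and gene symbol lists are of the kind called other here, since they only name the columns and lines of the matrices. Whether reads in introns were counted, and which annotation release was used, is not given in the sources used here; gene coordinates below come from the GRCm38 annotation at hand. The values were checked: all were whole numbers, and every sample listed 32285 genes.

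The labels give each group and biological replicate 3 times, as Day1, Day2 and Day3, and do not say what the day is. Barcodes were shared between the 3 samples of a replicate at 99.5% to 100% of the smaller sample, except in female CCI high replicate 1 (76.7% at the lowest), and between different libraries at no more than 0.416%. The counts of the 3 samples differed by less than Poisson noise (chi-square per degree of freedom 0.561 to 0.939), against 8.54 to 107 between biological replicates. The 3 samples were therefore treated as sequencing runs of 1 library, which leaves 16 libraries, 2 per group. The run with the most UMIs, Day3 in every library, was used; the total per sample over the 48 samples ran from 7911155 to 19984630 UMIs.

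Of 85781 barcodes in the runs used, nuclei with under 500 genes, under 800 UMIs or over 5% mitochondrially encoded UMIs were left out, which left 74703. Per library, the barcodes with the highest Scrublet-type doublet scores were left out, at a share proportional to the library's number of barcodes, which left 71235. Clustering used scanpy 1.11.5 (Python 3.11.15, scikit-learn 1.9.0, leidenalg 0.10.2) with 3000 variable genes, of which 2999 were used, 40 principal components, 19 neighbours and Leiden resolution 1.5 with seed 0, and gave 48 clusters. A cluster was named when at least 3 markers of a type were enriched at least 2-fold over the other clusters, no more than 75% of its nuclei came from 1 library and no more than 40% were called doublets. For excitatory neurons, markers of the leading region subset counted too. Left unnamed also were clusters with a tie between 2 types, with more markers of another type than of their own among the 10 leading genes, or with UMIs under 1/3 of the library median and either markers of 2 types or none of their own in that lead. So 33 clusters were named and 15 were not, and the unnamed held 22.4%, 17.9%, 24.0% and 16.0% of kept nuclei in female CCI high, CCI low, CCI sedentary and sham libraries, and 26.9%, 43.9%, 20.0% and 14.8% in the same male groups (means of 2). This naming rule was set after the clusters had been seen but before any comparison of groups. Named nuclei numbered 55044 of 12 types, and the shares below are of these.

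UMIs were summed per library and class for 7 classes: excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursor cells (OPC), microglia and vascular cells. A library entered a class with at least 20 nuclei, which left 12 libraries for vascular cells and 16 for the others. Each class was fitted in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling, 1 mean per group and the robust quasi-likelihood F test, two-sided, with 8 residual degrees of freedom (4 in vascular cells). The 14 contrasts were injury (CCI sedentary minus sham sedentary), low exercise and high exercise (each minus CCI sedentary), high minus low exercise and sex (females minus males), each averaged over the other factor, then injury, low and high exercise within each sex and their difference between the sexes (females minus males). The low and high exercise contrasts share the CCI sedentary libraries with the injury contrast, with the opposite sign, so their estimates are not independent. Adjusted p is Benjamini-Hochberg within class with a threshold of 0.05, over 60903 gene-class pairs in all. CPM values of tested genes use the library's total over the tested genes of the class times its TMM factor. CPM of Xist, Tsix and Y genes, of Gdf10, of clusters and of 3 counts, and those that compare glia with neurons, use all UMIs of the class or cluster. Errors are SE for log2 fold changes and SD between libraries for CPM and shares.

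The 20 gene lists cover reactive and homeostatic astrocytes, homeostatic and activated microglia, complement, interferon response, immediate early genes, neuron injury and axon growth, glutamate synapse, presynaptic release, GABA signalling, myelin, OPC differentiation, oxidative phosphorylation, glycolysis and lactate, cholesterol and lipid synthesis, glucocorticoid response, heat shock and chaperones, exercise-linked factors, and endothelial barrier and angiogenesis. They were tested with camera (limma 3.58.1, trend in variance allowed) on log2 CPM with a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the 39 pairs of list and class with at least 5 tested members within a contrast. A call by camera compares a list with the other genes of its class. Shares of types were compared, 4 libraries against 4, by exact two-sided permutation tests, whose smallest possible p is 0.0286; within a sex, 2 libraries against 2 cannot reach 0.05. The difference between the sexes in the change of a share was tested with limma on logit shares, after the shares had been seen, and values within a sex are given where both sexes moved without overlap in opposite ways.

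The contrasts, tests, filters, lists, markers, the first set of other settings and the rule for naming genes were chosen before the data were examined. The rule names, in injury, low exercise, high exercise and sex and in each class, the 3 genes up and the 3 down with the smallest p among those past 0.05 with a like sign in both sexes (in sex, in all 4 conditions), or 5 and 5 in the 2 classes with most calls. For high minus low exercise and the sex differences it names the 3 genes with the smallest p past 0.05, and for each list and class up to 4 members with the smallest p, past 0.05 or not. Symbols of predicted genes and clones, mitochondrially encoded genes and ribosomal protein genes were counted and not named. The list members were narrowed for length, by p alone, to 2 for a list past 0.05 and 1 for a list not past it; this narrowing was made after the values had been seen. Of 528 genes by contrast and class under the rule, 207 were carried through the alternatives.

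The procedure was tested on simulated data with 200 changed genes per class. For the injury contrast it recovered 17.9%, 56.9% and 84.6% of genes changed by a log2 fold of 0.5, 1 and 2 in excitatory neurons, and 0%, 7.81% and 67.2% in microglia. Of 117 calls there in excitatory neurons 13 were false, as were 5 of 51 in microglia. For sex, 8 of 62 calls in vascular cells and 3 of 90 in microglia were false. Each gene was simulated with the same spread in all libraries. In the data the male CCI low libraries differed more from each other than those of other groups, except in vascular cells. These rates need therefore not hold for the data. A simulated list of 40 genes raised by 0.5 gave camera p = 2.08e-28 with the preset and 2.12e-06 with an estimated correlation. The simulated genes varied independently of each other. This therefore does not show how either test does for lists whose genes vary together.

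Alternatives chosen before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, the Day1 and Day2 runs, the replicate number as a block, doublets kept, each library left out in turn, an estimated correlation for the lists, and for shares all nuclei as denominator and limma on logit shares. Added after seeing the data were: leaving out the 2 doubted libraries (male CCI low replicate 1 and female CCI high replicate 1), leaving out both male CCI low libraries, the 3 runs summed, excitatory neurons split by region, and the ribosomal protein share of a class as a covariate. Shares of mitochondrially encoded, ribosomal protein and oxidative phosphorylation UMIs per class were compared between conditions and between sexes by exact permutation tests, the latter only after the sex result had been seen. Nuclei of the 15 unnamed clusters were left out of the gene comparisons. Intervals for single shares are exact (Clopper-Pearson, 95%) and cover counting error only.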

Results

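Single-nucleus RNA counts were collected from cortex and hippocampus beside a controlled cortical impact (CCI), or from the same place after sham surgery, in male and female mice that were sedentary or, among CCI mice, had low or high exercise. The 16 libraries form 8 groups of 2: sham sedentary, CCI sedentary, CCI low and CCI high, in each sex. The libraries used held 8651092 to 19984630 UMIs each. Kept nuclei numbered 919 in female CCI high replicate 1 and 3118 to 6267 in the other 15 libraries.

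The named nuclei came from 12 types. The 7 classes tested gene by gene were excitatory neurons (23647 nuclei), oligodendrocytes (7878), inhibitory neurons (4971), astrocytes (4482), OPC (2178), microglia (1088) and vascular cells (554). Striatal neurons (6029) and thalamic or midline neurons (3835), types of regions beside the labelled block, were present in every library, at 0.780% to 20.8% and 4.10% to 10.3% of named nuclei. In male CCI low replicate 1, 46.5% of kept nuclei (exact 95% interval 44.9% to 48.1%) fell in 3 unnamed clusters led by cerebellar genes, against 0% to 0.0830% in the 4 sham libraries. For shares of named types, 0 of 36 exact permutation tests of 4 libraries against 4 had a p under 0.05 (smallest exact p = 0.143, adjusted p = 0.958). The smallest exact p such a test can give is 0.0286, so a single type could not pass 0.05 adjusted over 36 tests. Limma on logit shares, which has no such limit, called 0 at an adjusted p under 0.05, with 1 of 36 unadjusted (smallest adjusted p = 0.955). Microglia made up 1.88% ± 0.642 of named nuclei after injury against 2.50% ± 1.94 in sham (SD, n = 4 each, exact p = 0.600). The sexes went opposite ways without overlap: 1.72% ± 0.404 after injury against 0.896% ± 0.303 in sham in females, and 2.03% ± 0.991 against 4.11% ± 0.948 in males (SD, n = 2 each). This difference between the sexes had a limma adjusted p of 0.413 over 36 such tests, of which 3 had an unadjusted p under 0.05, and was tested after the values were seen. Of the other 35 differences, 1 also went opposite ways without overlap, the share of neuroblasts or neural progenitors with high exercise (limma adjusted p = 0.413). It was 0.501% ± 0.105 against 0.308% ± 0.151 in sedentary CCI libraries in females and 0.444% ± 0.139 against 0.749% ± 0.261 in males (SD, n = 2 each). Astrocytes made up 9.13% ± 2.55 against 7.52% ± 0.935 (exact p = 0.286). Among excitatory subsets, deep-layer cortical neurons made up 7.73% ± 0.680 after injury and 10.2% ± 1.97 in sham (exact p = 0.114, adjusted p = 0.943 over the subsets). With both sexes pooled, sedentary and exercised CCI libraries were likewise within their spread, though within 1 sex some shares lay apart without overlap. Microglia made up 2.01% ± 1.39 with low and 2.67% ± 1.09 with high exercise (exact p = 0.886 and 0.286). The low exercise mean includes male CCI low replicate 1 at 4.07%, against 1.125% to 1.66% in the other low exercise libraries.

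**Figure D1:**
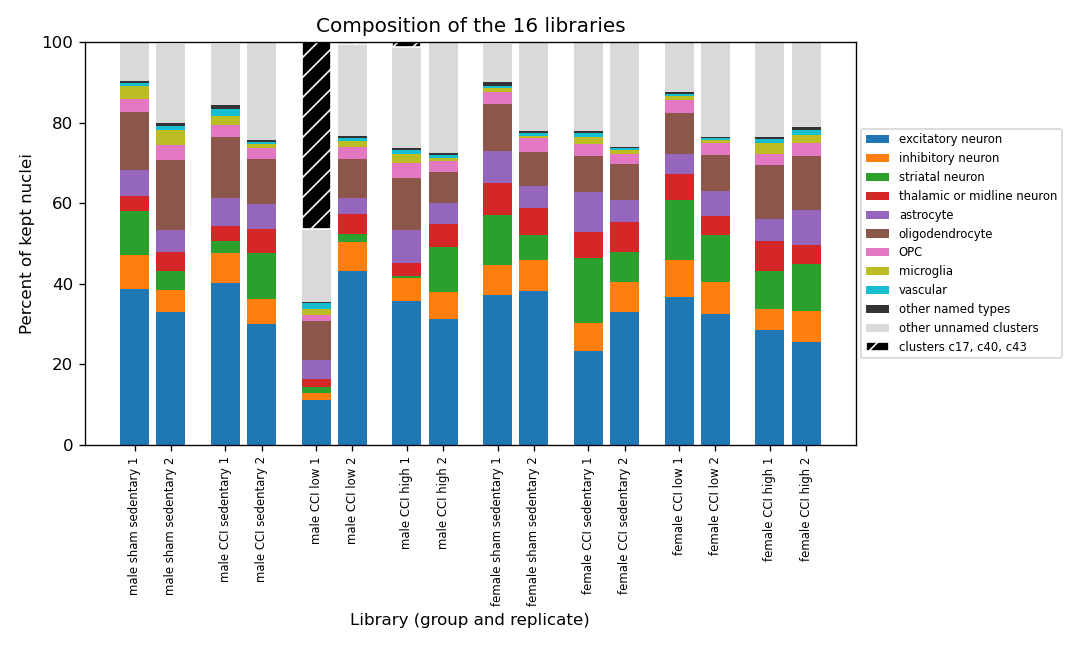
Percent of kept nuclei (y axis) by type in each of the 16 libraries (x axis, group and replicate); hatched black is the 3 unnamed clusters led by cerebellar genes. Male CCI low replicate 1 holds 46.5% of its nuclei there.

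The injury comparison asks what CCI changed in sedentary animals of both sexes. Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, rose together after injury in all 5 classes in which the list was tested, at the preset correlation. With an estimated correlation this call was lost in each (adjusted p = 0.549 in 4 classes and 0.680 in microglia). The median log2 fold change of the list was 0.38 in excitatory neurons, 0.41 in inhibitory neurons, 0.56 in astrocytes, 0.58 in oligodendrocytes and 0.50 in microglia. Of the measured members, 72 of 76, 70 of 76, 69 of 75, 74 of 76 and 56 of 60 were positive. In astrocytes Cox6c, a subunit of cytochrome c oxidase, stood at 256 ± 39.4 CPM after injury against 131 ± 30.1 in sham. Atp5e, a subunit of ATP synthase, stood at 107 ± 22.4 against 48.6 ± 16.6 (SD, n = 4 each), with no overlap between the sides. Genes of homeostatic microglia, the surveying state, fell together, with a median log2 fold change of -0.42 and 1 of 15 members positive (lost with an estimated correlation, adjusted p = 0.550). Heat shock and chaperone genes rose in excitatory neurons, astrocytes and oligodendrocytes (also lost with it, adjusted p = 0.550, 0.549 and 0.550).

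The camera calls for oxidative phosphorylation had adjusted p of 4.43e-25 in excitatory neurons, 9.73e-24 in inhibitory neurons, 9.41e-28 in astrocytes, 1.04e-28 in oligodendrocytes and 7.68e-05 in microglia. With an estimated correlation these became adjusted p = 0.549 in the first 4 classes and 0.680 in microglia. The microglial call ended without female sham sedentary replicate 1 (adjusted p = 0.0709). Adjusted over the list alone, 7 members rose in inhibitory neurons, 23 in astrocytes and 13 in oligodendrocytes, and 0 in excitatory neurons and microglia. None passed adjusted over all genes by edgeR, where 3428 of 60903 gene-class pairs had an unadjusted p under 0.05 and DESeq2 called 2. Other members with the smallest p were Atp5k at 0.72 ± 0.20 and Ndufv3 at 0.37 ± 0.12 on the log2 scale in excitatory neurons (SE). In inhibitory neurons they were Uqcr10 at 0.88 ± 0.21 and Cox6b1 at 0.66 ± 0.17. In glia they were Ndufb7 at 0.88 ± 0.23 and Atp5j2 at 0.75 ± 0.20 in oligodendrocytes, and Ndufc1 at 1.44 ± 0.61 and Cox7b at 1.12 ± 0.49 in microglia. Ribosomal protein UMIs moved with this list: they took 0.472% ± 0.0422 of excitatory neuron UMIs after injury against 0.355% ± 0.0838 in sham, and 0.537% against 0.388% in inhibitory neurons. The share was 0.861% against 0.581% in astrocytes, 1.04% against 0.713% in oligodendrocytes and 0.857% against 0.769% in microglia (exact p from 0.0571 to 0.571, adjusted p of at least 0.327). Mitochondrially encoded UMIs took 1.23% ± 0.234 against 0.903% ± 0.163 in excitatory neurons and 1.29% ± 0.124 against 0.968% ± 0.127 in inhibitory neurons (exact p = 0.0857 and 0.0286, the smallest possible, adjusted p = 0.386 and 0.327). With the ribosomal protein share as a covariate, an alternative added after the data were seen, the list was past 0.05 in 0 of the 5 classes (camera adjusted p = 0.398, 0.855, 0.930, 0.709 and 0.266), and its direction turned in inhibitory neurons.

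**Figure D2:**
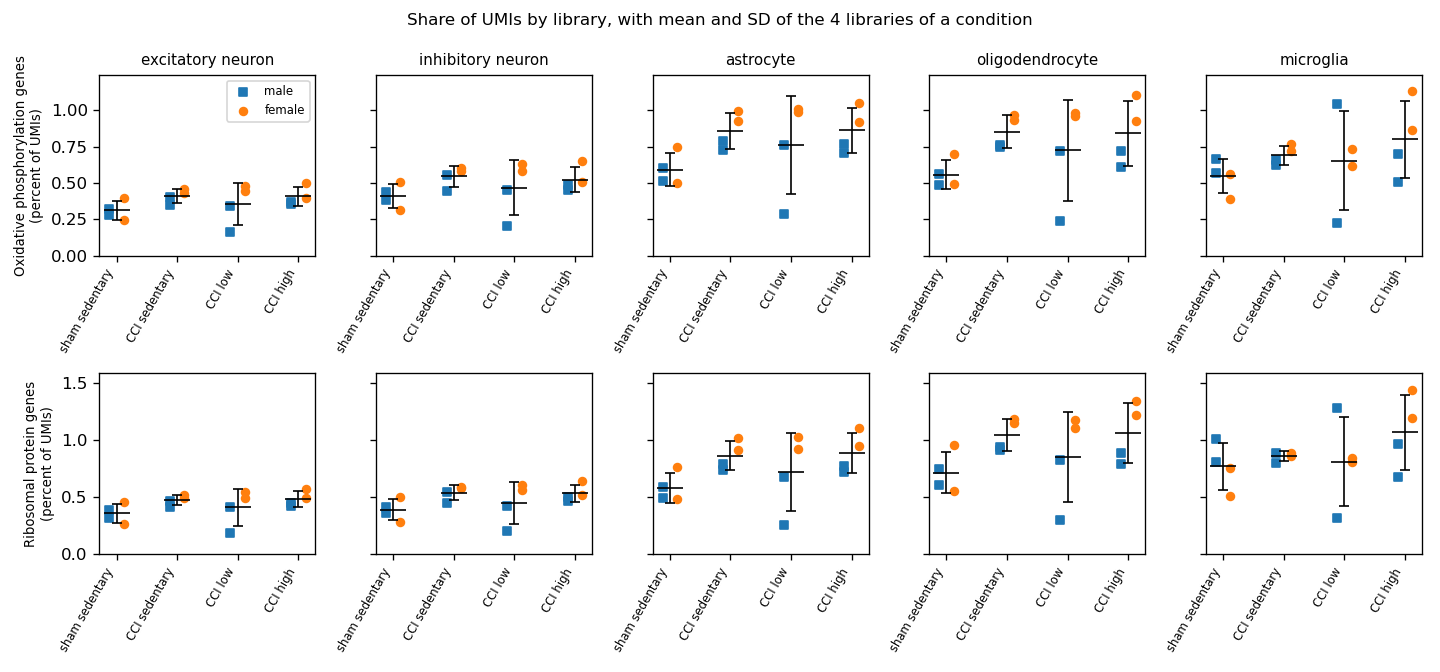
Percent of a class's UMIs (y axes) in oxidative phosphorylation genes (upper panels) and ribosomal protein genes (lower panels) by condition (x axis), for 5 classes; points are libraries, bars mean and SD of 4. Both shares were higher after injury than in sham in the mean of every class shown, and male CCI low replicate 2 is the lowest library.

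Other lists moved with injury as follows, each by camera, with the adjusted p at the preset correlation first. Heat shock and chaperone genes rose in excitatory neurons (adjusted p = 7.68e-05, and adjusted p = 0.550 with an estimated correlation), astrocytes (0.000231, and p = 0.549) and oligodendrocytes (0.000954, and p = 0.550). Positive were 24 of 29, 20 of 24 and 21 of 27 members. Their members with the smallest p were Hsp90aa1 at 0.31 ± 0.10 and Hspa8 at 0.46 ± 0.18 in excitatory neurons and Ahsa1 at 1.05 ± 0.32 and Hsp90ab1 at 0.48 ± 0.15 in astrocytes, where 3 members passed adjusted over the list alone. In oligodendrocytes they were Hspd1 at 0.48 ± 0.20 and Hsp90aa1 at 0.29 ± 0.13. Immediate early genes, switched on by neuronal activity, rose in excitatory neurons (0.00347, and p = 0.582 with an estimated correlation). Npas4 stood there at 0.39 ± 0.18 and Egr2 at 1.16 ± 0.54. The call ended without female sham sedentary replicate 1 (adjusted p = 0.216) or male CCI sedentary replicate 2 (adjusted p = 0.323). Genes of neuron injury and axon growth rose in excitatory neurons (0.000686, and p = 0.550 with an estimated correlation) and inhibitory neurons (0.00503, and p = 0.550). Positive were 20 of 22 and 16 of 19 members. Npy, a neuropeptide, stood at 0.48 ± 0.17 and Gap43, a growth cone protein, at 0.20 ± 0.10 in excitatory neurons. In inhibitory neurons Tubb2b stood at 0.70 ± 0.27 and Marcks at 0.39 ± 0.18. The first of these calls ended without male CCI sedentary replicate 2 (adjusted p = 0.0889). The second ended without that library (0.187), female sham sedentary replicate 1 (0.107) or male sham sedentary replicate 1 (0.0646). Glucocorticoid response genes rose in oligodendrocytes (0.0447, and p = 0.582 with an estimated correlation). Mt1, a metallothionein, stood there at 112 ± 10.4 CPM against 68.1 ± 20.1 and passed adjusted over the list alone, and Sgk1 stood at 0.51 ± 0.28. The call ended without female CCI sedentary replicate 2 (0.434), male CCI sedentary replicate 1 (0.225), female sham sedentary replicate 1 (0.198), male sham sedentary replicate 1 (0.0646) or 2 (0.0605). Under the ribosomal protein covariate the adjusted p were 0.855, 0.370 and 0.855 for heat shock in the 3 classes and 0.947 for immediate early genes. They were 0.855 for neuron injury in both neuron classes and for glucocorticoid response. The direction turned for immediate early genes and for neuron injury in inhibitory neurons.

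Genes of the glutamate synapse fell in excitatory neurons after injury, by a median log2 of -0.09, with 11 of 41 members positive (adjusted p = 0.00958, and adjusted p = 0.690 with an estimated correlation). Dlg1, a synaptic scaffold, stood at -0.21 ± 0.10. Nlgn2, which is also in the GABA signalling list, went against the fall at 0.29 ± 0.12. That call ended without female CCI sedentary replicate 1 (adjusted p = 0.0869) or female sham sedentary replicate 1 (adjusted p = 0.112). It turned upward with the ribosomal protein share as a covariate (adjusted p = 0.0226). The OPC class sums a cluster of 1912 nuclei led by Pdgfra and one of 266 nuclei led by Bcas1, with Enpp6 among its leading genes. A change in the mix of these clusters was not told apart from a change within nuclei. In OPC the differentiation list fell (adjusted p = 0.0309, and adjusted p = 0.549 with an estimated correlation): Enpp6, a marker of newly forming oligodendrocytes, stood at 156 ± 58.7 CPM against 251 ± 50.8 and passed adjusted over the list alone, and Bcas1 at -0.36 ± 0.14. This call ended without female CCI sedentary replicate 1 (0.331), female sham sedentary replicate 2 (0.275), male sham sedentary replicate 1 (0.137) or male CCI sedentary replicate 1 (0.136), and with the covariate (0.0948). The homeostatic microglia list fell (adjusted p = 0.00054, and adjusted p = 0.550 with an estimated correlation) with every library left out in turn and with the covariate (1.46e-05). Sall1, a transcription factor of microglial identity, stood at 175 ± 56.3 CPM against 322 ± 90.2, and Selplg at 361 ± 45.5 against 569 ± 170. The activated microglia list was not past 0.05 (adjusted p = 0.244, 11 of 18 positive). Spp1, an injury-linked secreted protein, ran from 33.4 to 381 CPM in the 4 CCI sedentary libraries and from 0 to 271 in sham. Also not past 0.05 were reactive astrocyte genes (adjusted p = 0.856, Cd44 at 0.91 ± 0.47), homeostatic astrocyte genes (0.249, Slc1a2 at -0.25 ± 0.12) and interferon response in astrocytes (0.469, Eif2ak2 at -0.41 ± 0.29). The same held for complement in microglia (0.480, Itgam at -0.69 ± 0.33), myelin (0.519, Apod at 0.30 ± 0.13), and endothelial barrier and angiogenesis in vascular cells (0.856, Col4a1 at -1.29 ± 0.64). Presynaptic release was at adjusted p = 0.232 in excitatory neurons (Rab3b at 0.78 ± 0.31) and 0.277 in inhibitory neurons (Rab3a at 0.32 ± 0.14). GABA signalling was at 0.856 (Gad1 at 0.33 ± 0.13) and 0.342 (Nlgn2 at 0.41 ± 0.17). Glycolysis and lactate ranged from 0.0678 in oligodendrocytes (Pgam1 at 0.49 ± 0.20) to 0.706 in microglia (Pfkfb3 at -0.70 ± 0.43). Cholesterol and lipid synthesis was at 0.898 in astrocytes (Elovl5 at -0.45 ± 0.18) and 0.534 in oligodendrocytes. Exercise-linked factors were at 0.247 in excitatory neurons, where Sirt3 stood at 31.3 ± 1.40 CPM against 38.2 ± 0.827, and at 0.886 in astrocytes. In 3 lists the median and mean differed in sign: GABA signalling in excitatory neurons (median -0.06, mean 0.05, test upward), cholesterol synthesis in astrocytes (0.03, -0.02, downward) and glucocorticoid response in astrocytes (-0.03, 0.02, upward, adjusted p = 0.856).

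Gene by gene, edgeR called 0 of 60903 gene-class pairs for injury, with 3428 at an unadjusted p under 0.05, and DESeq2 called 2. The count became 149 without male CCI low replicate 1, 170 without male CCI low replicate 2 and 43 without female sham sedentary replicate 2. The first 2 of these fits take their spread from the same remaining libraries, so they are not separate checks of the count. It was 1 without female CCI sedentary replicate 2, male sham sedentary replicate 1 or 2, and 197 without the 2 doubted libraries. Neither male CCI low library is a side of this comparison, but both enter the shared estimate of spread. Within males edgeR called 0 (1731 unadjusted, DESeq2 0; 75 and 77 without male CCI low replicate 1 or 2, 1 without male CCI sedentary replicate 1 or 2, 3 without male sham sedentary replicate 1). Within females it called 0 (3106 unadjusted, DESeq2 0; 17 and 19 without male CCI low replicate 1 or 2, 1 without female CCI sedentary replicate 2 or female sham sedentary replicate 2). For the difference between the sexes it called 0 (1623 unadjusted, DESeq2 0; 14 and 13 without male CCI low replicate 1 or 2, 1 without male CCI sedentary replicate 1). The oxidative phosphorylation list was past 0.05 in all 5 classes in females and in 4 in males. In males microglia gave a median of 0.13 (adjusted p = 0.496, against a median of 0.81 and 5.37e-07 in females). With an estimated correlation the adjusted p were 0.890 and 0.57, and 0.707 in the other 4 classes in males and 0.57 in females. Activated microglia genes rose in females (median 0.57, 16 of 18 positive, adjusted p = 0.00393, and adjusted p = 0.57 with an estimated correlation). In males its median was -0.24 (adjusted p = 0.357). The homeostatic microglia list had a median of -0.70 in males (adjusted p = 0.000657, and p = 0.707 with an estimated correlation) and -0.28 in females (adjusted p = 0.116). Differences of lists between the sexes were not tested.

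The low exercise comparison asks how CCI animals on low exercise differed from sedentary CCI animals. In the mean of both sexes, oxidative phosphorylation genes fell in all 5 classes, by median log2 of -0.26 in excitatory neurons, -0.32 in inhibitory neurons, -0.23 in astrocytes, -0.30 in oligodendrocytes and -0.29 in microglia. With an estimated correlation none of the 16 calls of this comparison held, and the adjusted p of those named in this paragraph were 0.672 to 0.713. Genes of the glutamate synapse rose in excitatory neurons, with a median of 0.20 and 40 of 41 members positive. This class sums cortical and hippocampal neurons. Hippocampal CA neurons made up 9.91% of named nuclei in male CCI low replicate 2 and 2.99% to 5.09% in the other low exercise libraries. They made up 2.08% to 6.98% in the CCI sedentary libraries. A change in this mix was not told apart from a change within nuclei. Genes of presynaptic release rose in both neuron classes, with 34 of 39 and 30 of 39 positive. Heat shock and chaperone genes fell in excitatory neurons, astrocytes and oligodendrocytes, and activated microglia genes fell with a median of -0.39. Most of these calls were lost without 1 library, male CCI low replicate 2, and in astrocytes and microglia the oxidative phosphorylation list then turned upward. That leaves replicate 1, the library with the cerebellar clusters, as the only male low exercise library. For oxidative phosphorylation the fall rests mainly on replicate 2. Genes of that list took 0.160% of excitatory neuron UMIs and 0.285% of astrocyte UMIs in it. The other low exercise libraries held 0.340% to 0.480% and 0.759% to 1.01%. The CCI sedentary libraries held 0.350% to 0.461% and 0.726% to 0.992%. In microglia replicate 1 was high, at 1.05% against 0.620% to 0.767% in the CCI sedentary libraries. The upward turn there can reflect it. For the other lists the loss can reflect either library.

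By camera the oxidative phosphorylation calls had adjusted p of 1.01e-07, 4.21e-09, 1.12e-08, 6.63e-11 and 0.00811 in the order above, and adjusted p = 0.681, 0.672, 0.672, 0.672 and 0.713 with an estimated correlation. Without male CCI low replicate 2 they were at adjusted p = 0.790, 0.513, 0.960 and 0.960, turning upward in astrocytes. In microglia the list was then raised, at 0.0120. The microglial call also ended without female CCI sedentary replicate 1 (0.118) or female CCI low replicate 2 (0.108). In females alone the list was not past 0.05 in any of the 5 classes (medians 0.08, 0.02, 0.04, 0.01 and -0.09). In males the medians were -0.60, -0.75, -0.53, -0.62 and -0.30 with adjusted p of at most 0.0109, which became at least 0.626 with an estimated correlation. The difference between the sexes was not tested for lists. Atp5g1 in inhibitory neurons stood at 71.7 ± 41.0 CPM against 110 ± 25.3. Atp5e in astrocytes stood at 69.4 ± 42.6 against 107 ± 22.4 (SD, n = 4 each). Others were Cox7a2 at -0.47 ± 0.21 and Cyc1 at -0.49 ± 0.22 in excitatory neurons and Ndufa7 at -0.77 ± 0.24 in inhibitory neurons. In glia they were Ndufa13 at -0.49 ± 0.25 in astrocytes, Ndufa6 at -0.53 ± 0.21 and Cox7c at -0.63 ± 0.27 in oligodendrocytes, and Ndufa10 at -0.82 ± 0.34 and Atp5g2 at -0.96 ± 0.40 in microglia. The ribosomal protein share was 0.408% ± 0.158 in excitatory neurons with low exercise against 0.472% ± 0.0422 (exact p = 0.600). It was 0.717% ± 0.342 against 0.861% ± 0.125 in astrocytes and 0.85% ± 0.396 against 1.04% ± 0.141 in oligodendrocytes. In all classes it was lowest of the 16 libraries in male CCI low replicate 2. With that share as a covariate the list turned upward in all 5 classes (adjusted p = 0.930, 0.653, 0.0881, 0.343 and 0.712).

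For the neuronal lists, camera gave adjusted p of 5.79e-07 for glutamate synapse in excitatory neurons and 0.000771 and 1.99e-05 for presynaptic release in excitatory and inhibitory neurons. It gave 0.0138 and 0.0256 for GABA signalling. With an estimated correlation the adjusted p were 0.672, 0.672, 0.672, 0.681 and 0.672. Without male CCI low replicate 2 they were at 0.174, 0.0784, 0.0404, 0.790 and 0.513. Of these 5, presynaptic release in inhibitory neurons alone held. The GABA call in excitatory neurons also ended without female CCI sedentary replicate 2 (0.116). In inhibitory neurons it ended without female CCI low replicate 2 (0.0941), female CCI sedentary replicate 1 (0.137) or male CCI sedentary replicate 1 (0.0516). Under the ribosomal protein covariate, glutamate synapse and presynaptic release stayed past 0.05 (adjusted p = 0.0316 for all 3) and GABA signalling did not (0.653 and 0.234). Sv2b, a synaptic vesicle protein, stood at 27.9 ± 6.98 CPM against 16.9 ± 3.25 in inhibitory neurons. Unc13b, a vesicle priming factor, stood at 65.2 ± 10.5 against 44.9 ± 5.35 there, and both passed adjusted over the list alone. In excitatory neurons Cacng2 stood at 0.31 ± 0.12, Homer1 at 0.31 ± 0.15, Syn1 at 0.21 ± 0.09, Sv2b at 0.20 ± 0.11, Gabrb1 at 0.31 ± 0.17 and Gabrb2 at 0.24 ± 0.14. In inhibitory neurons Gabrb1 stood at 0.45 ± 0.16 and Gabra4 at 0.43 ± 0.15.

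Heat shock and chaperone genes had adjusted p of 0.0279 in excitatory neurons, 0.000771 in astrocytes and 0.00886 in oligodendrocytes (adjusted p = 0.681, 0.672 and 0.672 with an estimated correlation). They were 0.880, 0.0415 and 0.785 without male CCI low replicate 2. The first also ended without female CCI low replicate 2 (0.0941), female CCI sedentary replicate 2 (0.0791) or male CCI sedentary replicate 2 (0.121). The third ended without female CCI sedentary replicate 1 (0.113) or male CCI sedentary replicate 2 (0.0605). With the ribosomal protein share as a covariate the adjusted p were 0.760, 0.0785 and 0.653. Hsp90ab1 stood at 404 ± 149 CPM against 548 ± 63.4 and Ahsa1 at 23.3 ± 13.7 against 39.2 ± 4.96 in astrocytes. Hspa1a stood at -1.24 ± 0.39 and Calr at -0.42 ± 0.14 in excitatory neurons. In oligodendrocytes Hspa5 stood at -0.55 ± 0.20 and Pdia6 at -0.56 ± 0.23. Myelin genes fell in oligodendrocytes (adjusted p = 0.00501, and adjusted p = 0.681 with an estimated correlation; 4 of 23 positive), with Apod at -0.35 ± 0.13. Activated microglia genes fell (0.00104, and p = 0.672 with an estimated correlation; 4 of 18 positive). Ctsl, a lysosomal protease, stood at 59.0 ± 25.8 CPM against 122 ± 11.2. Spp1 stood at 10.4 ± 7.22 against 152 ± 159, with 381 in female CCI sedentary replicate 2. Its low exercise values lay under the 71.9 CPM that 3 counts make in the shallowest library of this class. The myelin and activated microglia calls ended without male CCI low replicate 2 and with the covariate (adjusted p = 0.653, turned upward, and 0.265). The myelin call also ended without female CCI low replicate 1 (0.123), female CCI sedentary replicate 2 (0.197) or male CCI sedentary replicate 2 (0.0605). Glycolysis and lactate genes fell in astrocytes (0.0210, and p = 0.672 with an estimated correlation), with Eno1 at -0.44 ± 0.21 and Pdk4 at -0.80 ± 0.42. The call ended without male CCI low replicate 2 (0.988), female CCI low replicate 1 (0.0736) or 2 (0.0653), female CCI sedentary replicate 1 (0.254) or male CCI sedentary replicate 2 (0.0930). It turned upward with the covariate (0.835).

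Lists not past 0.05 with low exercise included immediate early genes in excitatory neurons (adjusted p = 0.197, Npas4 at -0.65 ± 0.19) and neuron injury and axon growth in excitatory and inhibitory neurons (0.316 and 0.197, Npy at -0.84 ± 0.19 and -1.09 ± 0.37). In excitatory neurons Npy passed adjusted over the list alone. Others were glucocorticoid response in oligodendrocytes (0.668, Mt1 at -0.98 ± 0.21, past adjusted over the list alone) and in excitatory neurons (0.307, Per2 at 0.56 ± 0.17), and complement in microglia (0.266, C1qb at -1.05 ± 0.41). Glucocorticoid response in excitatory neurons had a median of -0.09, a mean of 0.09 and a test upward. The median was also against the test for immediate early genes in inhibitory neurons (-0.12), cholesterol synthesis in astrocytes (-0.03) and oligodendrocytes (0.02) and OPC differentiation (-0.05). Gene by gene, edgeR called 0 of 60903 pairs for low exercise, with 4643 at an unadjusted p under 0.05, and DESeq2 called 4. Fits without male CCI low replicate 1 or 2 rest on 1 male low exercise library, with its spread taken from the other groups. In them the distance of that library from the sedentary ones cannot be told from an effect of exercise. In males edgeR called 3 pairs (7421 unadjusted, DESeq2 4), named here after their values were seen. Cspg5, a proteoglycan, stood in OPC at 424 ± 50.5 CPM against 978 ± 107 (log2 -1.22 ± 0.23, adjusted p = 0.0308; SD, n = 2 each). In oligodendrocytes Npy stood at 9.86 ± 2.47 against 53.5 ± 2.23 (adjusted p = 0.0459) and Dlc1 at 128 ± 36.3 against 27.3 ± 15.7 (adjusted p = 0.0459, SD, n = 2 each). Npy was a leading gene of an inhibitory neuron cluster, and RNA carried over from other cells was not separated from that of the oligodendrocytes. The male count without male CCI low replicate 1 or 2 is not given here, since it rests on 1 low exercise library. It was 5 without female CCI high replicate 1 and 1 without female CCI high replicate 2. Leaving out any of female CCI low 1 or 2, female CCI sedentary 1 or 2, male CCI high 1 or 2 or male CCI sedentary 1 left 0. The Cspg5 call ended without any of these or male CCI low 2 or male CCI sedentary 2 (adjusted p 0.0553 to 0.453). The Npy and Dlc1 calls ended without any library other than male CCI low 1, female sham sedentary 1 and female sham sedentary 2 (0.0602 to 0.641, and 0.0689 to 0.823). All 3 also ended with DESeq2 (0.0563, 0.152 and 0.0954), the Day1 run (0.0884, 0.434 and 0.454), the Day2 run (0.187, 0.486 and 0.310), the 3 runs summed (0.106, 0.412 and 0.412) and the ribosomal protein covariate (0.970, 0.288 and 0.106). Doublets kept ended that of Cspg5 (0.0884). In females edgeR called 0 (1446 unadjusted, DESeq2 0; 1 without female CCI sedentary replicate 2, male CCI low replicate 1 or 2). For the difference between the sexes it called 0 (3663 unadjusted, DESeq2 1).

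The high exercise comparison asks how CCI animals on high exercise differed from sedentary CCI animals. UMIs of Reln, the secreted protein reelin (chromosome 5, 21884454 to 22344702, GRCm38), were fewer in nuclei of the microglia class with high exercise in all 4 libraries: 31.2 and 9.87 CPM in females and 8.76 and 17.9 in males, against 266, 409, 157 and 117 in the sedentary libraries (log2 -3.75 ± 0.55, adjusted p = 0.0115). These values rest on few UMIs: 2, 1, 1 and 1 with high exercise, against 25, 29, 21 and 7. In the sedentary libraries 9 of 60, 5 of 52, 2 of 111 and 3 of 47 nuclei held them, and single nuclei held 7, 13, 20 and 4. No gene list was called in the planned test: camera called 0 of 39 pairs at the preset correlation, with 6 at an unadjusted p under 0.05, and 0 with an estimated correlation. Some lists were past 0.05 in other settings, given below. Reln was at 8.96 and 19.8 CPM in male sham and 300 and 60.3 in female sham. Over all libraries it was far higher in inhibitory neurons, at 402 ± 99.7 CPM, than in microglia at 103 ± 121, and it stood at 34.5 ± 12.9 in excitatory neurons, 23.6 ± 18.4 in astrocytes and 11.9 ± 8.13 in oligodendrocytes (SD, n = 16). RNA carried over from other cells was not separated from that of the microglia. Among members with the smallest p of their lists were Per2, a clock gene, in excitatory neurons at 37.5 ± 5.91 CPM against 23.5 ± 3.34, and Hif3a in astrocytes at 158 ± 42.3 against 97.9 ± 33.3, each past adjusted over its list alone.

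Gene by gene, edgeR called 1 of 60903 pairs for high exercise (2152 at an unadjusted p under 0.05), the Reln call, and DESeq2 called 4. The Reln call ended without female CCI high replicate 2 (adjusted p = 0.151), female CCI sedentary replicate 2 (0.0630), male CCI high replicate 1 (0.235) or male CCI sedentary replicate 1 (0.251). It also ended with the Day1 or Day2 run (log2 -2.98 and -3.13, adjusted p = 0.412 and 0.492). The count was 17 without either male CCI low library and 15 without the 2 doubted libraries. Lists nearest to a call were immediate early genes in excitatory neurons (adjusted p = 0.125, Nr4a3 at 26.2 ± 4.29 CPM against 19.4 ± 4.25), glutamate synapse (0.125, Cacng2 at 0.25 ± 0.12) and presynaptic release in excitatory and inhibitory neurons (0.125 for both, Syp at 0.15 ± 0.10 and Unc13b at 0.35 ± 0.17). Under that covariate the last 3 were past 0.05 and upward (0.0200, 0.0499 and 0.0240), and without the 2 doubted libraries 6 lists were. Oxidative phosphorylation had medians of 0.00, -0.04, -0.01, -0.04 and 0.12 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes and microglia (adjusted p of at least 0.296). Exercise-linked factors were at 0.296 in excitatory neurons and astrocytes, with Sirt3 at 37.8 ± 2.04 CPM against 31.3 ± 1.40 and Ppargc1a at -0.31 ± 0.15. In males immediate early genes rose in excitatory neurons (median 0.14, adjusted p = 0.0333, and adjusted p = 0.997 with an estimated correlation). In males edgeR called 0 (1423 unadjusted, DESeq2 1; 2 without either male CCI low library, 1 without male CCI sedentary replicate 1). In females it called 0 (1988 unadjusted, DESeq2 1). The female count was 9 and 8 without male CCI low replicate 1 or 2, 4 without female CCI high replicate 2, and 1 without female CCI sedentary 2, female sham sedentary 1 or 2, or male CCI high 1 or 2. High against low exercise gave 0 by edgeR (3256 unadjusted, DESeq2 1). Its fits without male CCI low replicate 1 or 2 rest on 1 male low exercise library.

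One gene differed between the sexes in its response to high exercise: Mid1, an X-linked ubiquitin ligase (chromosome X, 169685199 to 170005736, GRCm38), in inhibitory neurons. In females it stood at 39.8 and 41.5 CPM with high exercise against 10.6 and 6.10 in sedentary CCI libraries. In males it stood at 2.20 and 3.67 against 18.8 and 56.9, which made a difference of 5.88 ± 0.83 on the log2 scale (females minus males, adjusted p = 0.0139). The UMIs behind these values were 20 and 64 against 10 and 7 in females and 2 and 3 against 27 and 53 in males. In sham it stood at 20.1 and 40.3 in females and 16.1 and 13.6 in males. It was the 1 pair called by edgeR for this difference (1352 unadjusted, DESeq2 2). The call ended without female CCI high replicate 1 (adjusted p = 0.0620) or 2 (0.324), female CCI sedentary replicate 2 (0.173), or male CCI high replicate 1 (0.307) or 2 (0.145). It also ended with the Day1 or Day2 run (log2 difference 4.00 and 4.12, adjusted p = 1 for both), the 3 runs summed (4.47, adjusted p = 0.783) and the 2 doubted libraries left out (0.244). In all, 2 pairs were called without either male CCI low library.

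The sex comparison sets 8 female against 8 male libraries. Beyond the sex chromosomes, most calls lay in oligodendrocytes, astrocytes and OPC: of 141 calls for autosomal genes higher in females, 50 were in oligodendrocytes, 49 in astrocytes and 29 in OPC, against 10 in inhibitory and 3 in excitatory neurons. None of the autosomal calls in either direction lay in microglia or vascular cells, where simulated sex changes of log2 1 were recovered at 41.4% and 13.3%, against 83.3% in astrocytes, so this does not show that these classes differed less. Classes were not tested against each other, and the 216 calls in all became 68 to 3257 without 1 library. In astrocytes Nrgn, a calmodulin-binding protein abundant in neurons, stood at 295 ± 52.6 CPM in females against 146 ± 44.1 in males. Calm2, a calmodulin, stood at 466 ± 58.6 against 284 ± 56.1 (SD, n = 8 each), and neither gene's sides overlapped. In oligodendrocytes Gap43 stood at 125 ± 30.9 against 73.3 ± 19.5, Nrgn at 308 ± 82.2 against 178 ± 49.3 and Hras, a small GTPase, at 78.7 ± 20.9 against 42.9 ± 15.8. In OPC Pcp4, another calmodulin-binding protein, stood at 438 ± 135 against 193 ± 71.7. RNA carried over from neurons was not separated from that of these glia. Higher in males were Sntg1 in astrocytes, at 170 ± 67.8 against 90.4 ± 25.1, and Tmod1 in oligodendrocytes, at 284 ± 39.99 against 197 ± 25.3.

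Female and male libraries also differed in the share of ribosomal protein UMIs, beyond the classes with autosomal calls: 0.895% ± 0.193 in females against 0.627% ± 0.181 in males in astrocytes (exact p = 0.0135, adjusted p = 0.0473). It was 1.08% ± 0.240 against 0.748% ± 0.209 in oligodendrocytes (exact p = 0.00995, adjusted p = 0.0473) and 1.07% ± 0.233 against 0.743% ± 0.199 in vascular cells (exact p = 0.0101, adjusted p = 0.0473). In OPC, at 0.832% ± 0.202 against 0.602% ± 0.173, it was not past 0.05 when adjusted (exact p = 0.0280, adjusted p = 0.0601; SD, n = 8 each). Oxidative phosphorylation UMIs took 0.891% ± 0.183 against 0.644% ± 0.173 in astrocytes, 0.883% ± 0.196 against 0.605% ± 0.180 in oligodendrocytes and 0.879% ± 0.202 against 0.611% ± 0.175 in vascular cells (exact p = 0.0162, 0.0121 and 0.0127, adjusted p = 0.0485, 0.0473 and 0.0473). Mitochondrially encoded UMIs took 1.32% ± 0.211 against 0.987% ± 0.135 in oligodendrocytes (exact p = 0.00389, the smallest of 21 such tests, adjusted p = 0.0473). In astrocytes they took 0.863% ± 0.282 against 0.753% ± 0.119 (exact p = 0.382). With the ribosomal protein share as a covariate, the median absolute log2 fold change of the 147 called autosomal genes outside the neuron classes went from 0.73 to 0.53, and all 147 had the same sign. Log2 fold changes, females minus males, were 1.06 ± 0.13 for Nrgn (adjusted p = 1.14e-05), 0.70 ± 0.11 for Calm2 (0.000656) and -0.93 ± 0.19 for Sntg1 (0.0258) in astrocytes. They were 0.78 ± 0.11 for Gap43 (0.00178), 0.83 ± 0.13 for Nrgn (0.00488), 0.93 ± 0.15 for Hras (0.00546) and -0.53 ± 0.09 for Tmod1 (0.0108) in oligodendrocytes. The value was 1.21 ± 0.14 for Pcp4 (3.89e-07) in OPC. In neurons Npy was higher in females in excitatory cells, at 25 ± 5.75 CPM against 12.4 ± 5.53 (adjusted p = 0.000918). Ano2, a calcium-activated chloride channel, was higher in females in inhibitory cells, at 19.5 ± 9.47 against 3.40 ± 3.86 (adjusted p = 0.00854). Of X-linked genes, Tmsb4x stood at 618 ± 169 against 341 ± 109 in astrocytes and Bex2 at 228 ± 74.2 against 89.4 ± 31.8 in microglia (adjusted p = 0.00164 and 0.0272). Sntg1 was no longer past 0.05 without any 1 of 6 libraries (female CCI high 2, female CCI low 1, female CCI sedentary 1, female sham sedentary 2, male CCI high 1, male CCI sedentary 1; adjusted p 0.0743 to 0.141). The Tmod1 call ended without any 1 of 3 (female CCI low 1, male CCI sedentary 1, male sham sedentary 1; 0.0535 to 0.0674), and that of Ano2 without male CCI sedentary replicate 1 (0.0579). That of Bex2 ended without any library other than male CCI high 1, male CCI low 1, male CCI low 2 and male sham sedentary 2 (0.0561 to 0.436). Other settings also ended calls: the Day1 run for Sntg1 (0.310), Tmod1 (0.0912) and Bex2 (0.574), and the Day2 run for Sntg1 (0.212), Hras (0.0875) and Bex2 (0.208). So did the 3 runs summed for Sntg1 (0.206) and Bex2 (0.162), doublets kept for Ano2 (0.0655) and Bex2 (0.0546), DESeq2 for Bex2 (0.0747), and the ribosomal protein share as a covariate for Sntg1 (0.143), Hras (0.0559) and Ano2 (0.0705).

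Sex-linked genes matched the labels in all 16 libraries: in excitatory neurons Xist, the RNA that silences an X chromosome, stood at 1202 to 1733 CPM in females and 0.113 to 1.60 in males. The Y genes stood in males at 38.9 to 44.0 for Ddx3y, 94.7 to 133 for Uty, 28.6 to 42.99 for Kdm5d and 95.5 to 169 for Eif2s3y, and at most at 0.441 in females. Tsix, antisense to Xist, stood at 126 to 228 CPM in females and 1.36 to 3.58 in males. In all, edgeR called 216 of 60903 pairs (6814 unadjusted; DESeq2 123), 170 higher in females and 46 higher in males. They were 29 X-linked calls higher in females, 26 Y-linked calls higher in males, and 141 autosomal calls higher in females against 20 higher in males. The count ranged from 68 without male CCI sedentary replicate 1 to 3257 without male CCI low replicate 1, and was 907 without male CCI low replicate 2 and 453 without female sham sedentary replicate 1. It was also below 216 by over 1.5 times without female CCI high 2 (76), female CCI low 1 (86), female CCI low 2 (107), female CCI sedentary 1 (78), female sham sedentary 2 (104), male CCI high 1 (99), male CCI high 2 (114), male sham sedentary 1 (91) or male sham sedentary 2 (139).

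**Figure D3:**
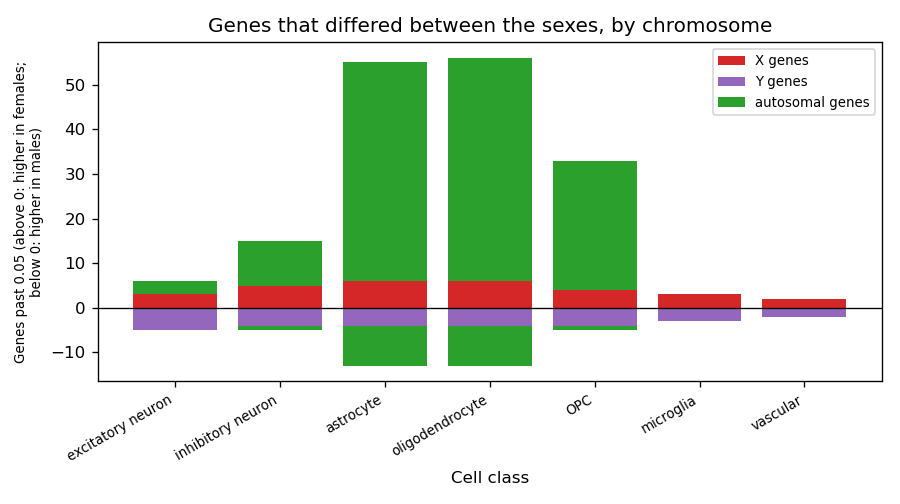
Gene-class pairs past 0.05 (y axis; above 0 higher in females, below 0 higher in males) in each class (x axis), by chromosome of the gene. Autosomal calls higher in females number 49 in astrocytes, 50 in oligodendrocytes and 29 in OPC.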

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

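In this part the tests of free or cytoplasmic RNA (for injury and for sex), of neuronal RNA in glia, of the sex of a library, of splits with equal numbers of each condition, of splits for autosomal calls and of Bergmann glia in a cluster of their own were chosen only after the result was seen. The test against lists matched on genomic span and level was chosen after the gene list calls were known, but before its own value was.

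Genes of oxidative phosphorylation rose after injury in all 5 classes tested (lost with an estimated correlation, adjusted p = 0.549 to 0.680), and the mean share of ribosomal protein UMIs was also higher in each (adjusted p of at least 0.327). A shift of genes with a short genomic span in general is argued against as the whole cause. In 5 of 5 classes the median of the list lay above the central 95% of 10000 lists matched on that span and on level (medians 0.12, 0.16, 0.19, 0.19 and 0.14, upper ends 0.17, 0.22, 0.29, 0.27 and 0.29), though such a shift could account for a part. Length of the transcript itself was not matched, so a shift of short transcripts stays open. Genes were drawn singly, so this range is too narrow for a list whose members vary together. Free or cytoplasmic RNA carried by the nuclei stays open and had the value it needs: with the ribosomal protein share as a covariate the list was raised and past 0.05 in 0 of the 5 classes by camera. The medians went from 0.38 to 0.03 in excitatory neurons (interquartile range 0.265 before, 0.153 with it), from 0.41 to 0.00 in inhibitory neurons (0.276 and 0.261), from 0.56 to -0.05 in astrocytes (0.33 and 0.417), from 0.58 to 0.04 in oligodendrocytes (0.353 and 0.287) and from 0.50 to 0.28 in microglia (0.519 and 0.521). The covariate was itself higher after injury, so a rise of mitochondrial and ribosomal genes as a response of the tissue to injury is not excluded by this and was not tested apart from it.

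Autosomal genes were higher in females in astrocytes, oligodendrocytes and OPC, as was the mean share of ribosomal protein UMIs (adjusted p = 0.0473, 0.0473 and 0.0601), which was also higher in vascular cells, with no such call (0.0473). Free or cytoplasmic RNA, as far as it follows that share, is argued against as the whole cause: with the ribosomal protein share as a covariate, the median absolute log2 fold change of the 147 called autosomal genes in glia was 0.733 times that without it (0.53 against 0.73; per gene a median ratio of 0.760, interquartile range 0.524 to 0.971), though 34 genes fell under 0.5 of their value and it may account for a part; free RNA that follows mitochondrially encoded UMIs, higher in females in oligodendrocytes (1.32% against 0.987%, adjusted p = 0.0473), was not tested and stays open. RNA with the composition of excitatory or inhibitory neuron nuclei, carried in glial nuclei, is argued against as the whole cause. Of 128 called raised genes, 27.3% had a higher CPM in these neurons than in the glial class, which is under the bound set for this cause. Of 31593 tested genes, which also cover microglia and vascular cells, 43.4% did. Mixing in such RNA raises only genes with a higher CPM in those neurons. It may account for a part, and the called genes include Nrgn and Pcp4. Neuronal RNA of another composition, such as that of cytoplasm or of other neurons, was not tested and stays open. Glia held a median of 1182 UMIs per nucleus against 3494 in neurons. Free RNA takes a larger share of the CPM where nuclei hold fewer UMIs. The low percent therefore does not decide on free RNA of neurons, and neuronal RNA in glia in general was left undecided. Sex itself is a factor of the design and stays open as a biological explanation.

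In male CCI low replicate 1, 46.5% of kept nuclei lay in 3 clusters that enter no comparison, against 0% to 0.0830% in the sham libraries; this is a signal in data that the comparisons leave out. A cluster of 1445 nuclei carried Gabra6 at 958 CPM, Fat2 at 479 and Cbln3 at 441, genes of cerebellar granule cells, and a cluster of 111 nuclei carried Slc1a3 at 2626 and Gria1 at 4776. A library of the other sex is argued against, for its excitatory neurons, by Xist at 1.07 CPM there. Sex-linked genes were not read in the 3 clusters, so this does not bear on where their nuclei came from. Tissue from outside the block stays open by the test planned for it, since Gdf10, a gene of Bergmann glia, was at 0 CPM in astrocytes of this library (3 counts would be 8.64 CPM; highest elsewhere 14.1); that bound was wrong, because Gdf10 was at 134 CPM in the cluster of 111 nuclei, so that Bergmann glia lay in a cluster of their own and not among the astrocytes. Cerebellar tissue in the dissected block, or nuclei of another sample mixed in, is therefore a candidate explanation, and no biological explanation was tested.

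The remaining items are given without weighing. Over 80 groups of 4 libraries, 3 held a library far from the others, where chance gives about 1 in 20 groups. Astrocytes made up 8.91% of named nuclei in female sham sedentary replicate 1 against 6.88% to 7.17% in the other sham libraries. Oligodendrocytes made up 10.7% in male CCI high replicate 2 against 17.1% to 17.6% in the other CCI high libraries, and 27.3% in male CCI low replicate 1 against 11.5% to 12.7% in the other CCI low libraries. Mid1 in inhibitory neurons differed between the sexes in its response to high exercise by 5.88 on the log2 scale, by a test of the difference itself; it was 4.00, 4.12 and 4.47 with the Day1 run, the Day2 run and the 3 runs summed, no longer past 0.05 (adjusted p = 1, 1 and 0.783).

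Other splits of the same libraries were used to ask whether chance can be excluded, and over all splits drawn it cannot for the counts that were not 0. For injury gene lists 7 of 35 splits gave at least the real 15 (highest other 23), and for low exercise lists 15 of 35 gave at least 16 (highest 26). Among the 18 splits with equal numbers of each sex on both sides, the real one included, 2 did so for injury (highest other 15). For low exercise 10 of these 18 did (highest other 21). For high exercise 17 of 35 gave at least 1 pair of gene and class (highest 45, the split by sex). For sex 9 of 100 gave at least 216 pairs (highest 4376); these were first drawn at 60, with 7 as large, and then at 100. All 8 other sex splits as large put unequal numbers of a condition on the 2 sides and part the 2 male CCI low libraries. Of 80 splits drawn with equal numbers of each condition on both sides, 1 gave at least 216 pairs, the real one (highest other 204), but the real count holds X-linked and Y-linked calls that a split by sex is bound to give. For the 161 autosomal calls, 11 of 100 splits gave as many (highest other 4247), over which chance cannot be excluded. Of the 80 balanced splits 2 gave as many, a share under 0.05, but the other of the 2 gave more than the real one, 198. The 80 are a draw from the balanced splits, so this does not exclude chance. In excitatory neurons Xist and the Y genes parted all 16 libraries by sex without overlap. Where the real count was 0, every split gives at least as many and the splits decide nothing: 35 of 35 for pairs in injury (highest other 77), in low exercise (5078) and in high against low exercise (4196), and 35 of 35 for lists in high exercise (18). Splits that call many times the real count point to a structure of the libraries. For low exercise all 4 splits over 200 pairs had unequal numbers of each sex on the 2 sides and part the 2 male CCI low libraries, and splits with equal numbers gave at most 5. For high against low exercise all 5 such splits part these libraries, and 1 of them, with 369 pairs, had equal numbers of each sex. For injury the split with 77 pairs was that by replicate number, and the real count with a replicate block was also 0. The largest unnamed cluster, of 9376 nuclei, took a higher share in replicate 2 than in replicate 1 in 7 of 8 groups.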

How the results depend on the processing

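The settings without the doubted libraries (male CCI low 1, female CCI high 1), without both male CCI low libraries, with 3 runs summed, by region subset and with the ribosomal protein share as covariate were chosen after seeing the data; the rest were chosen before the data were examined. Counts are gene-class pairs past 0.05, in edgeR unless named. Changes by over 1.5 times were as follows, and the cause was not tested, except that fewer libraries enter where some are left out. With no filter on low counts the count was 199 for injury, 545 for low exercise, 200 for high exercise, 62 for high against low exercise, 1629 for sex, 57 for injury in males, 61 for injury in females, 1476 for low exercise in males, 42 in females, 27 for high exercise in males, 154 in females, and 12, 129 and 14 for the sex difference of injury, low exercise and high exercise. The DESeq2 Wald test gave 2 for injury, 4 for low exercise, 4 for high exercise, 1 for high against low exercise, 123 for sex, 1 for high exercise in males, 1 in females, and 1 and 2 for the sex difference of low exercise and high exercise. The Day1 run gave 0 for high exercise, 12 for low exercise in males and 0 for the sex difference of high exercise, and the Day2 run 0, 5 and 0. Doublets kept gave 1 for low exercise and 13 in males. Without the 2 doubted libraries the counts were 197 (injury), 5537 (low exercise), 15 (high exercise), 2031 (high against low exercise), 3397 (sex), 123 and 15 (injury in males and in females), 10252 and 1 (low exercise in males and in females), 3 and 26 (high exercise in males and in females), and 30 and 2832 (sex difference of injury and of low exercise). Without both male CCI low libraries they were 157 (injury), 17 (high exercise), 73 and 15 (injury in males and in females), 1 (low exercise in females), 2 and 5 (high exercise in males and in females), and 13 and 2 (sex difference of injury and of high exercise). With 3 runs summed they were 5 for low exercise in males, 1 for high exercise in females and 0 for the sex difference of high exercise, and by region subset 1 for low exercise. With the ribosomal protein share as covariate they were 240 (injury), 15 (low exercise), 7 (high exercise), 7 (high against low exercise), 970 (sex), 110 and 41 (injury in males and in females), 58 and 2 (low exercise in males and in females), 1 and 4 (high exercise in males and in females), and 1, 13 and 3 (sex difference of injury, low exercise and high exercise). The replicate numbers were not taken to pair the libraries, since in no class did every pair of groups correlate above 0.1, though more did so than correlated below -0.1 in neurons and oligodendrocytes: of 28 pairs of groups, 15 correlated above 0.1 and 2 below -0.1 in excitatory neurons (-0.35 to 0.29), 9 and 1 in inhibitory neurons, 8 and 3 in oligodendrocytes, 5 and 6 in microglia, 1 and 2 in astrocytes and 2 and 1 in OPC. Among the 4 groups of the injury comparison, 6 of 6 pairs were above 0.1 in excitatory neurons (0.17 to 0.29), 4 in inhibitory neurons, 4 in oligodendrocytes, 1 in microglia and 0 in astrocytes and OPC. The replicate block gave 1 for low exercise, 2 for high exercise, 1 for high against low exercise, 7 for low exercise in males and 1 for high exercise in females, with 0 for injury, 277 for sex and 33 gene lists (17 for injury, 16 for low exercise and 0 for high exercise), and moved no other count by over 1.5 times. Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 0 to 170 for injury, 0 to 5621 for low exercise, 0 to 17 for high exercise, 0 to 2196 for high against low exercise, 68 to 3257 for sex, 0 to 77 and 0 to 19 for injury in males and in females, 0 to 10255 and 0 to 1 for low exercise, 0 to 2 and 0 to 9 for high exercise, 0 to 14, 0 to 3083 and 0 to 2 for the sex difference of injury, low exercise and high exercise, and 0 in every run for shares of types. In every class but vascular, the 2 male CCI low libraries differed more from each other than those of any other group (root mean square log2 difference 0.83 in excitatory neurons, 0.36 to 0.51 in the other groups). Fits without replicate 1 leave replicate 2 as the only male low exercise library. Their large low exercise counts therefore cannot be told from the distance of that library. Of gene lists by camera, 31 were past 0.05 (15 injury, 16 low exercise, 0 high exercise): 0 with an estimated correlation, 14 with the covariate (7, 4 and 3), and 22 to 41 without 1 library (12 to 17, 3 to 23 and 0 to 2); high exercise had 6 without the doubted libraries. With the covariate the direction turned for injury in immediate early genes (adjusted p = 0.947) and glutamate synapse (0.0226) of excitatory neurons and in neuron injury and oxidative phosphorylation (0.855 for both) of inhibitory neurons. For low exercise it turned in oxidative phosphorylation (0.930, 0.653, 0.0881, 0.343 and 0.712 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes and microglia), glycolysis in astrocytes (0.835) and myelin (0.653). The lists it brought past 0.05 included myelin, lower after injury (2.05e-08). Of named genes, log2 changes turned for Cr1l in astrocyte injury (Day1 0.073), Elovl5 in astrocyte injury (Day2 0.11), Pdia3 in microglia injury (Day1 0.18, Day2 0.030), Nr4a1 in inhibitory_neuron low exercise (Day1 -0.19), Atp5g2 in microglia low exercise (Day1 0.10, Day2 0.081), Scd1 in astrocyte low exercise (Day1 -0.32), Stat3 in astrocyte high exercise (Day1 0.17, Day2 0.12, runs summed 0.10), Eif2ak2 in astrocyte high exercise (Day1 0.052), Ldhb in astrocyte high exercise (Day2 0.0735), Ldhb in microglia high exercise (Day2 -0.10) and Cldn5 in vascular high exercise (replicate block 0.0725). Without 1 library, Parp14 in microglia injury ran from -0.81 to 0.46, Stat3 in astrocyte high exercise from -0.27 to 0.12 and C1qa in astrocyte high exercise from -0.19 to 0.95, and the adjusted p of oxidative phosphorylation with low exercise from 2.82e-20 to 0.960 in astrocytes and from 1.67e-15 to 0.118 in microglia. The other results of named genes kept direction and side of 0.05 in 2208 cases, lost the call in 40 and gained it in 55; for lists 66 kept and 47 lost it; and without 1 library genes gave 3166, 71 and 44, and lists 446 kept and 48 lost. Depth limits rare genes most in vascular cells and microglia, where 3 counts in the shallowest library used are 83.1 and 71.9 CPM, against 17.2 in astrocytes and 1.07 in excitatory neurons.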

Other observations

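The test without both male CCI low libraries, and the genes named from it, were chosen only after the result was seen. With those 2 libraries out of the shared estimate of spread, edgeR called 157 gene-class pairs for injury, where all 16 libraries gave 0 (3428 unadjusted; DESeq2 2). In oligodendrocytes 71 genes were higher and 2 lower after injury, and 22 of those higher belong to oxidative phosphorylation and 18 are ribosomal protein genes. In astrocytes 54 were higher and 5 lower, 10 and 11 of them of these kinds; in OPC 12 and 2, in microglia 6 and 1, and in inhibitory neurons 3 and 1. Cox6c in astrocytes stood at a log2 fold change of 0.99 (adjusted p = 0.000189), Apoe in oligodendrocytes at 0.68 (0.00636), and Ntng1, a neuronal axon guidance protein, in microglia at 2.61 (0.000123). Of the pairs, 8 were among the 240 called with all 16 libraries and the ribosomal protein share as covariate. Leaving out replicate 1 alone or replicate 2 alone takes the spread from the same remaining libraries, so those fits are no separate check. The count of 0 with all libraries stays the result as planned.

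Cerebellar clusters also held 1.02% of kept nuclei in male CCI high replicate 1 and 0.399% in male CCI low replicate 2.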
